A study of Mus musculus with 7 samples.

How the data were processed

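Gene expression was measured in 7 samples of microglia, the resident macrophages of the brain. Per the labels, cells negative for a viability dye and positive for the leukocyte marker CD45 and the myeloid marker CD11b were sorted from brain cell suspensions. The mice were 5xFAD animals, a transgenic model that forms amyloid plaques, on the C57BL/6 strain. They carried either intact B2m or no functional B2m. Total RNA was purified with a column kit for small samples, labelled with biotin by a whole-transcript kit and hybridized to 1 array per sample.

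The deposited values were log2 expression per probe set. The authors made them with RMA, which corrects background, normalizes between arrays and summarizes probes, in Affymetrix Expression Console 1.1, per the submitters' processing notes. The genome build and annotation of the array were not given in the sources used here. The value table held 28846 rows between 3.57 and 14.34 with array medians from 7.68 to 7.75, so no further normalization was applied. A probe annotation paired 19572 rows with 1 gene symbol and 0 with several, and listed no gene for the other 9274. All 19572 were matched by Entrez identifier to a reference gene table of assembly GRCm38.p6, which gave current symbols for 19505 genes. That table was used for names, the order of neighbouring genes and gene spans, and no coordinate is printed. Where 1 of 55 genes had several probe sets, the set with the highest mean over the 7 arrays was kept. Rows whose identifiers carry neg or pos tags, 5222 and 1324, were read as negative and positive control rows from those tags alone. Some negative control rows were bright, since B2m in wildtype arrays lay above 99.8% to 99.9% of them and not above all. They are therefore a rough guide to background.

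Samples were grouped by the genotype in the labels, giving 3 B2m wildtype and 4 B2m knockout arrays. The labels gave no batch, sex or litter. Replicate numbers follow deposit order and pair no samples. No label states that arrays came from separate animals, so p-values measure the spread between these samples, which may in part be technical. For arrays, the number of arrays limits the precision.

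A gene was tested when its value lay above the array's median over named genes in at least 3 of the 7 arrays, which left 10004 genes. Knockout was compared with wildtype in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A looser count took genes at an unadjusted p under 0.05 and at least 1.5-fold. The main test, the alternatives and the gene lists were set before the data were examined. Gene names in the text follow a rule. It takes B2m and, among called genes whose groups did not overlap, the 12 largest differences in each direction. Directions with fewer than 12 were filled by the smallest unadjusted p among genes of at least 1.5-fold without overlap, which are stated not to pass. Predicted genes, RIKEN clones, pseudogenes, microRNAs and olfactory or vomeronasal receptors were not named under these parts. It adds up to 4 members of each list with the smallest unadjusted p, called genes near B2m, and sex-linked genes. A name outside the rule is said to have been chosen after its values were seen.

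The 20 pathway lists were MHC class I presentation, MHC class II presentation, type I interferon-stimulated genes, interferon-gamma-induced genes, disease-associated microglia, homeostatic microglia, inflammatory cytokines and chemokines, NF-kappa-B feedback and targets, complement and Fc receptors, phagocytosis and lysosome, cholesterol synthesis, cholesterol efflux and lipid storage, oxidative phosphorylation, glycolysis and hypoxia response, ribosomal proteins, cell cycle, immediate early and dissociation response, heat shock proteins, oxidative stress response, and TGF-beta signalling. The 13 cell type lists covered CD8 T cells, T cells, natural killer cells, B cells, neutrophils, monocytes, border-associated macrophages, dendritic cells, astrocytes, oligodendrocytes, neurons, endothelial and mural cells, and erythroid cells. The 29 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the 29. Camera with an estimated correlation, camera on ranks and fry, which asks whether a list's genes move 1 way on balance, were alternatives.

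Neighbours of B2m were counted in gene order, 50 tested genes on each side, because the sources named no build for the array. The planned windows in megabases were not run for that reason, although the gene order came from start positions in the reference gene table. Called genes among neighbours were compared with those elsewhere by Fisher's exact test, two-sided. Alternatives set in advance were no filter or a stricter filter (70th percentile) on dim genes, an intensity trend with or without a robust prior, array weights, repeated quantile normalization, centring on array medians, the mean of probe sets, every row of the table, and leaving out each array. A sex covariate was planned where Y-linked genes varied by more than 1 between arrays and was not run, since their range was 0.219. Removal of the trend with gene span, the omission of 2 arrays at a time, exact permutation of list medians, narrower or wider neighbourhoods and a fit without B2m and its neighbours were chosen after seeing the results of the planned tests. Leaving out wildtype replicates 1 and 2 left 1 wildtype array, so a call kept or lost in that fit decides nothing.

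The fit was tested on simulated arrays drawn for the 10004 genes of the knockout and wildtype comparison, in 20 simulations with 200 changed genes each. It recovered 47.8% of genes changed by 0.5 on the log2 scale, 98.7% of those changed by 1 and 100% of those changed by 2, and called 0.1% of unchanged genes. A list shifted by 0.3 was called in 20 of 20 simulations, with 0.05 calls of other lists per simulation. The simulated genes were independent of each other, which real list members are not. The Benjamini-Hochberg adjustment passes larger p-values when more genes change, and 5 genes passed in the real data. The recovered shares can therefore overstate what the real fit recovers. Plac8, as an example, differed by 1.1 (SE 0.30) and did not pass in limma (adjusted p = 0.315).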

Results

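Transcript levels were measured with 1 expression array per sample in microglia sorted from the brains of 5xFAD mice, a transgenic amyloid model of Alzheimer's disease. B2m was intact in 3 samples and disrupted in 4. B2m encodes beta-2-microglobulin, the light chain of MHC class I molecules. Without it, few MHC class I molecules reach the cell surface, and few CD8+ T cells develop. The design text set the microglial transcription profiles of both genotypes side by side, and the series title places the study in work on brain CD8+ T cells and amyloid pathology. Values were log2 expression after RMA by the authors, and differences are given as knockout minus wildtype. Over 10004 tested genes, correlations between arrays ran from 0.946 to 0.98. The first principal component held 33.6% of the variance. Its scores were -19.1, -9.85 and 1.24 in the wildtype arrays and 9.10, 17.0, 7.57 and -5.94 in the knockout arrays, so knockout replicate 4 lay among the wildtype arrays. The second held 23.6% and set knockout replicate 4 (-21.7) apart from the others (-4.06 to 8.81).

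B2m mRNA (Entrez Gene 12010) was 13.41 ± 0.017 (SD, n = 3) in wildtype and 10.42 ± 0.13 (SD, n = 4) in knockout microglia. It fell by 2.99 on the log2 scale (SE 0.10, limma adjusted p = 1.54e-07), a 7.95-fold difference with a 95% confidence interval of 6.78 to 9.33. The genotypes did not overlap, with 13.39 to 13.42 in wildtype and 10.24 to 10.56 in knockout arrays. The knockout values still lay above 97.7% to 98.4% of the array's negative control rows. Which part of the transcript the probes read was not analysed here.

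Of the 10004 tested genes, 5 passed the threshold in limma, 2 higher and 3 lower in knockout microglia. The largest difference was in Spint1 (Entrez Gene 20732), a Kunitz-type inhibitor of serine proteases. It fell by 4.75 (SE 0.13, adjusted p = 2.17e-08) from 12.02 ± 0.037 (SD, n = 3) to 7.26 ± 0.22 (SD, n = 4). Kcnip3 (Entrez Gene 56461), which encodes the calcium-binding protein calsenilin, fell by 2.25 (SE 0.14, adjusted p = 2.44e-05). Knockout values of both genes lay between the 62.8th and 79.5th percentiles of the negative control rows, so no folds are given. Gatm (Entrez Gene 67092), the first enzyme of creatine synthesis, rose by 1.95 (SE 0.10, adjusted p = 6.03e-06) from 9.94 ± 0.11 (SD, n = 3) to 11.89 ± 0.082 (SD, n = 4), 3.86-fold. Slamf7 (Entrez Gene 75345), a signalling receptor of the SLAM family on immune cells, rose by 1.19 (SE 0.16, adjusted p = 0.0320) from 7.63 ± 0.18 (SD, n = 3) to 8.82 ± 0.28 (SD, n = 4). Its values lay below the 95th percentile of the negative control rows in both genotypes, so no fold is given. They lay between the 72.6th and 79.7th percentiles in wildtype and the 86.2nd and 93.7th in knockout arrays. All 4 knockout arrays exceeded all 3 wildtype arrays for Gatm and Slamf7. The Slamf7 call was lost without wildtype replicate 1 (adjusted p = 0.309) or 2 (0.311) and without knockout replicate 1 (0.0841), 2 (0.115) or 3 (0.155). Its lowest adjusted p over 17 alternatives was 0.00415. With B2m and its 100 tested neighbours left out of the fit, 0 genes passed in limma, 1171 reached an unadjusted p under 0.05, and the Slamf7 adjusted p was 0.158. B2m, Spint1, Kcnip3 and Gatm passed in each of 18 alternatives.

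**Figure D1:**
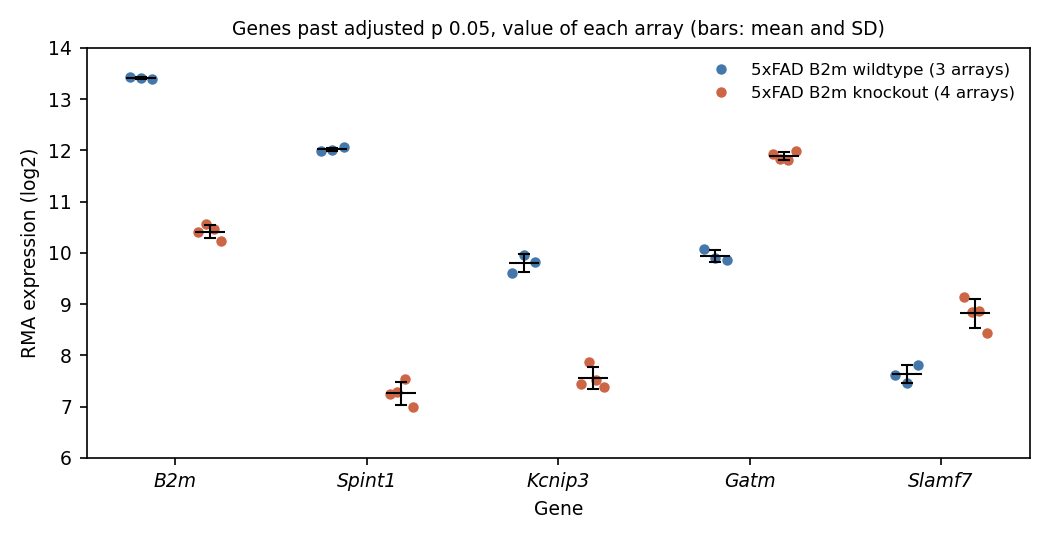
RMA expression (log2) of the 5 genes past the threshold in each array, with wildtype arrays in blue, knockout arrays in orange, and black bars for the mean and SD of each group. B2m, Spint1 and Kcnip3 were lower and Gatm and Slamf7 higher in all 4 knockout arrays than in all 3 wildtype arrays.

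Looser thresholds took in genes that did not pass correction. At an unadjusted p under 0.05, limma counted 1193 genes, 839 higher and 354 lower, and other splits of the same 7 arrays gave up to 1679. With at least 1.5-fold, 96 were counted, 60 higher and 36 lower, and this count was 58 without wildtype replicate 1 and 249 without wildtype replicate 3. The groups did not overlap in 10.9% of genes, where chance gives 5.71% on average. This share was not counted over the other splits, and genes that move together between arrays can shift it, so chance is not excluded. Among genes without overlap that did not pass, Mmp12, the macrophage elastase, was closest to the threshold at -0.71 (SE 0.11, limma adjusted p = 0.102). Other lower values that did not pass belonged to Slc6a20a, an amino acid transporter (-0.62), the sialomucin Podxl (-0.60), the kinase anchor Akap12 (-0.82), Epas1, which encodes a hypoxia-inducible factor (-0.86), Pcnx (-0.74), Ckap2l (-0.68), the muscle glycogen phosphorylase Pygm (-0.62) and the carboxylate transporter Slc16a9 (-0.64). Higher values that did not pass belonged to the sialyltransferase St8sia6 (0.61), the respiratory complex I subunits Ndufb9 (0.62) and Ndufv2 (0.69), Rpl22l1 (0.59), the calcium-binding protein S100a4 (0.92), the importin Kpna1 (0.64), Itgb1bp1 (0.61), Tmem208 (0.72), the myosin light chain Myl2 (0.80) and Sinhcaf (0.64). Their limma adjusted p values lay between 0.183 and 0.315. All values of Slc6a20a, Podxl, Akap12, Pcnx, Ckap2l, Pygm, Kpna1 and Myl2 lay below their array's 95th percentile of the negative control rows (9.35 to 9.55). The filter itself, at array medians of 7.925 to 7.988 over named genes, lay below that percentile, so list members can share this limit. Without wildtype replicate 3, 7 genes were higher and 19 lower past the threshold, among them Tmem208, Myl2, Akap12, Epas1, Pcnx and Slc16a9. The last 4 were lower in wildtype replicate 3 than in wildtype replicates 1 and 2, as Epas1 at 8.91 against 9.72 and 9.62. Endothelial markers, described below, had the same order, and whether endothelial RNA accounts for these genes was not tested.

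The knockout allele was made at B2m on chromosome 2, so the order of genes around it was examined. Gatm was the next tested gene on 1 side of B2m, and Spint1 and Kcnip3 lay 36 and 27 tested genes away on opposite sides. Of the 100 tested neighbours, 3 passed the threshold, against 1 of 9903 genes elsewhere (Fisher's exact test, two-sided p = 3.85e-06). The 1 elsewhere was Slamf7, on chromosome 1. At an unadjusted p under 0.05 the share was 21.0% among the neighbours and 11.8% elsewhere (Fisher's exact test, two-sided p = 0.00797), with differences in both directions. Ckap2l at -0.68, Dnajc17 at -0.50 and Tmem62 at 0.48 had the smallest unadjusted p among the neighbours that did not pass, and the last 2 were chosen after their values were seen. Other neighbours known for roles in microglia, chosen after their values were seen, showed small differences. Mertk, a phagocytic receptor kinase, differed by 0.0035 (SE 0.11), Il1a by 0.011 (SE 0.12), Il1b by 0.14 (SE 0.15) and Sirpa by 0.012 (SE 0.097). None of these passed, with limma adjusted p from 0.749 to 0.993.

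**Figure D2:**
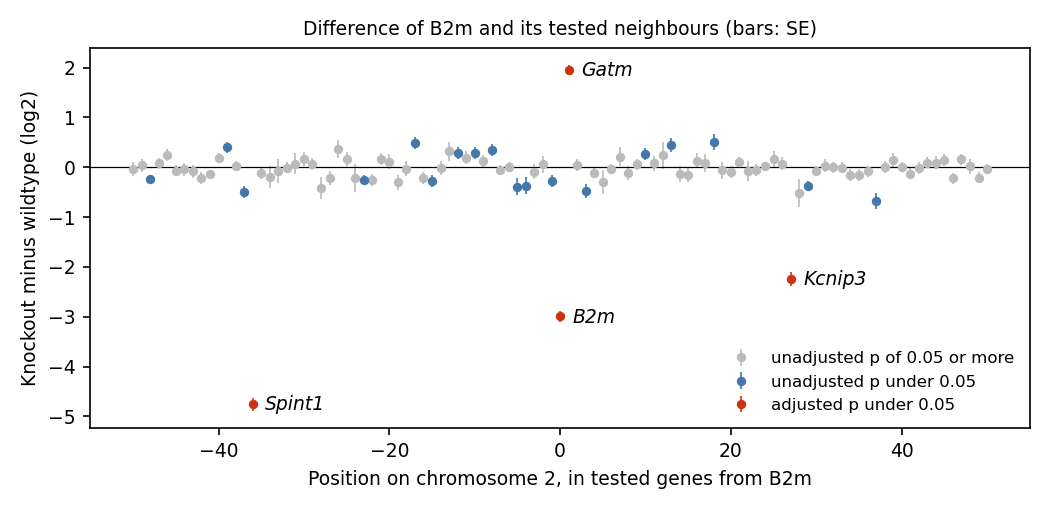
Difference between knockout and wildtype (log2, points, with SE as bars) of B2m and the 50 tested genes on each side, in gene order along chromosome 2. Spint1, Gatm and Kcnip3 stand apart at -4.75, 1.95 and -2.25, while the grey and blue neighbours did not pass the adjusted threshold.

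Genes of oxidative phosphorylation and of the ribosome were higher as groups in knockout microglia. Of 64 tested oxidative phosphorylation genes, 62 had differences above 0, with a median of 0.33 (camera adjusted p = 2.19e-21, adjusted p = 0.684 with an estimated correlation). Over all genes 0 passed in limma and 39 were higher and 0 lower at an unadjusted p under 0.05, while 33 passed when adjusted over the list alone. Ndufb9 was 9.16 ± 0.20 (SD, n = 3) in wildtype and 9.78 ± 0.052 (SD, n = 4) in knockout arrays. Ndufv2, the ATP synthase subunit Atp5j and the complex III subunit Uqcr11 differed by 0.69 (SE 0.13), 0.56 (SE 0.12) and 0.67 (SE 0.18). All 56 tested ribosomal protein genes had differences above 0, with a median of 0.21 (camera adjusted p = 3.11e-13, adjusted p = 0.684 with an estimated correlation). Among them 0 passed in limma over all genes or adjusted over the list alone, and 16 were higher and 0 lower at an unadjusted p under 0.05, led by Rpl17 at 0.42 (SE 0.12) and Rpl35a at 0.37 (SE 0.11). Both lists were lowest in wildtype replicate 1, with array medians of -0.40 for oxidative phosphorylation and -0.30 for ribosomal proteins, against 0.007 and 0.033 in wildtype replicate 3. The array medians separated the genotypes for oxidative phosphorylation (exact permutation test, two-sided p = 0.0286, the smallest that 35 splits allow, adjusted p = 0.276), as they did for cholesterol synthesis and cell cycle with the same p, and not for ribosomal proteins (exact permutation p = 0.0857). For oxidative phosphorylation the separation was narrow, with 0.007 in wildtype replicate 3 and 0.013 in knockout replicate 4. The ribosomal median was 0.13 without wildtype replicate 1 and 0.14 with the gene span trend removed. Deviations of each array's genes from their mean correlated across genes with gene span, with Spearman's rho of 0.361, 0.136 and -0.149 in wildtype and -0.243, -0.254, -0.197 and 0.222 in knockout arrays, where genes are not independent replicates. Endothelial markers, described with the cell types, were highest in wildtype replicates 1 and 2. Without both of these arrays, which left 1 wildtype array, the median was 0.13 for oxidative phosphorylation and 0.052 for ribosomal proteins.

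Among lists of microglial states, the disease-associated set, which microglia raise around amyloid plaques, was higher in knockout samples by a small median of 0.13 over 35 tested genes (camera adjusted p = 0.00297, adjusted p = 0.684 with an estimated correlation). Of its members 27 lay above 0, 5 were higher and 0 lower at an unadjusted p under 0.05, and 0 passed in limma over all genes or adjusted over the list alone. Lilrb4a, an inhibitory receptor, differed by 0.37 (SE 0.11), the chemokine Ccl6 by 0.37 (SE 0.12), Ch25h, which makes an oxysterol, by 0.58 (SE 0.21) and the lectin Lgals3 by 0.48 (SE 0.19). Homeostatic microglial genes had a median of -0.013 over 33 genes (camera adjusted p = 0.718), with Upk1b at 0.30 (SE 0.13) and Lag3 at -0.33 (SE 0.15). In that list 1 gene was higher and 1 lower at an unadjusted p under 0.05 and 0 passed in limma over all genes or adjusted over the list alone. The disease-associated call was lost without wildtype replicate 2 (median 0.078, adjusted p = 0.0587) or knockout replicate 1 (median 0.11, adjusted p = 0.0508). Without both wildtype replicates 1 and 2, which left 1 wildtype array, the median of the disease-associated list was 0.026. Its median was 0.21 without wildtype replicate 3 and 0.084 after repeated quantile normalization (adjusted p = 0.0115).

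Type I interferon-stimulated genes were also higher as a group, with a median of 0.12 and 22 of 31 tested genes above 0 (camera adjusted p = 0.0213, adjusted p = 0.684 with an estimated correlation). Slfn2 differed by 0.35 (SE 0.10), Oas1a, a sensor of double-stranded RNA, by 0.59 (SE 0.20), Rtp4 by 0.40 (SE 0.14) and the transcription factor Irf7 by 0.51 (SE 0.19), and none of these passed. In limma 0 of the list passed over all genes or adjusted over the list alone, and 7 were higher and 0 lower at an unadjusted p under 0.05. The call was lost without wildtype replicate 1 (median 0.11, adjusted p = 0.0915) or 2 (median 0.062, adjusted p = 0.126) and without knockout replicate 1 (median 0.064, adjusted p = 0.205) or 2 (median 0.089, adjusted p = 0.110). The median was 0.19 without wildtype replicate 3. It was 0.036 without both wildtype replicates 1 and 2, the arrays highest in endothelial markers, which left 1 wildtype array. The call was also lost with a stricter filter (median 0.075, adjusted p = 0.275), and with the gene span trend removed the median was 0.060 (adjusted p = 0.0318), and after repeated quantile normalization 0.079 (adjusted p = 0.0249). Over the alternatives that kept at least 2 wildtype arrays, the adjusted p ran from 0.000394 to 0.684. Interferon-gamma-induced genes had a median of -0.063 over 20 genes (camera adjusted p = 0.269), with Gbp7 at -0.49 (SE 0.23). MHC class I presentation genes, which supply peptides and heavy chains to the complex that B2m completes, had a median of 0.085 over 22 genes (camera adjusted p = 0.123). The proteasome genes Psme2, Psmb8 and Psmb9 differed by 0.33 (SE 0.12), 0.43 (SE 0.16) and 0.39 (SE 0.17). The heavy chain genes H2-K1 and H2-D1, chosen after their values were seen, differed by 0.050 (SE 0.12) and 0.092 (SE 0.15). MHC class II presentation genes went both ways around a median of 0.012 over 11 genes, with a mean of -0.0090 (camera adjusted p = 0.993), H2-Aa at -0.36 (SE 0.16) and H2-DMb1 at 0.27 (SE 0.12). In these 3 lists 0 genes passed in limma over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 0 interferon-gamma-induced genes, 3 MHC class I genes (all higher) and 2 MHC class II genes were counted.

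Heat shock proteins were lower as a group, with a median of -0.16 and 12 of 15 tested genes below 0 (camera adjusted p = 0.0228, adjusted p = 0.684 with an estimated correlation). Hspa1a differed by -0.41 (SE 0.14) and Hspb1 by -0.39 (SE 0.15), 2 members were lower and 0 higher at an unadjusted p under 0.05, and 0 passed in limma over all genes or adjusted over the list alone. The call was lost without wildtype replicate 1 (median -0.077, adjusted p = 0.212) or 3 (median -0.147, adjusted p = 0.0850) and without knockout replicate 2 (median -0.094, adjusted p = 0.0514), 3 (median -0.10, adjusted p = 0.153) or 4 (median -0.204, adjusted p = 0.0779). It was also lost with no filter (median -0.155, adjusted p = 0.0503), with array weights (median -0.179, adjusted p = 0.0522) and without wildtype replicate 1 and knockout replicate 4 together (median -0.11, adjusted p = 0.355).

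The other 11 pathway lists did not pass in camera. Cell cycle genes had a median of 0.043 over 23 genes (adjusted p = 0.122), and 2 of them, the mitotic kinases Plk1 at 0.67 (SE 0.17) and Cdk1 at 0.83 (SE 0.21), passed in limma when adjusted over the list alone and not over all genes. Wildtype and knockout means were 7.81 and 8.48 for Plk1 and 8.07 and 8.89 for Cdk1. All lay below the 95th percentile of the negative control rows (9.35 to 9.55). Inflammatory cytokines and chemokines had a median of 0.081 over 20 genes (adjusted p = 0.399), with the chemokine Cxcl2 at 0.35 (SE 0.14). NF-kappa-B feedback and targets had a median of -0.029 over 22 genes (adjusted p = 0.972), with Ier3 at 0.28 (SE 0.095). Complement and Fc receptors had a median of 0.0094 over 15 genes (adjusted p = 0.902), with properdin, Cfp, at 0.43 (SE 0.14). Phagocytosis and lysosome genes had a median of 0.033 over 29 genes (adjusted p = 0.431), with the cholesterol transporter Npc1 at 0.46 (SE 0.16). Cholesterol synthesis had a median of 0.052 over 16 genes (adjusted p = 0.284), with Fdps at 0.45 (SE 0.15). Cholesterol efflux and lipid storage had a median of 0.054 over 14 genes (adjusted p = 0.512), with the lipid droplet lipase Pnpla2 at -0.35 (SE 0.12), Fabp3 at 0.76 (SE 0.26) and the droplet coat protein Plin2 at 0.31 (SE 0.13). Glycolysis and hypoxia response had a median of 0.047 and a mean of -0.037 over 26 genes (adjusted p = 0.994). There the peptide hormone gene Adm was 10.11 ± 0.14 (SD, n = 3) in wildtype and 8.97 ± 0.79 (SD, n = 4) in knockout arrays, and Vegfa differed by -0.49 (SE 0.18). Immediate early and dissociation response genes, which tissue digestion can induce, had a median of 0.024 over 25 genes (adjusted p = 0.902), with Ier2 at 0.37 (SE 0.097) and Nr4a2 at -0.55 (SE 0.19). Oxidative stress response had a median of 0.11 over 20 genes (adjusted p = 0.217), with Gpx4 at 0.40 (SE 0.15). TGF-beta signalling had a median of -0.016 and a mean of 0.014 over 17 genes (adjusted p = 0.994), with Smad7 at 0.30 (SE 0.12). Over the 224 distinct genes of these 11 lists, 0 passed in limma over all genes, and 23 were higher and 4 lower at an unadjusted p under 0.05. Apart from Plk1 and Cdk1, 0 passed when adjusted over the list alone.

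Markers of other cell types that the CD45 and CD11b gate can hold also differed between arrays. Neutrophil markers had a median of 0.47 over 17 tested genes, with 16 above 0 (camera adjusted p = 0.0178, adjusted p = 0.722 with an estimated correlation). Array medians were highest in knockout replicate 4 at 1.25 and knockout replicate 3 at 0.37, while knockout replicate 1 was the lowest of all at -0.61. The granule peptide gene Camp differed by 0.68 (SE 0.29), and the abundant neutrophil calprotectin genes S100a8 and S100a9 by 0.88 (SE 0.40) and 0.66 (SE 0.31). Monocyte markers had a median of 0.26 over 12 genes, with 7 above 0 and 5 below (camera adjusted p = 0.0220, adjusted p = 0.684 with an estimated correlation). In limma 4 of them passed when adjusted over the list alone and 0 over all genes. These were S100a4 at 0.92 (SE 0.18), Ms4a4c at 0.69 (SE 0.17), Plac8 at 1.1 (SE 0.30) and S100a6 at 0.98 (SE 0.28). Without knockout replicate 4 the medians were 0.094 for neutrophil markers (adjusted p = 0.409) and 0.10 for monocyte markers (adjusted p = 0.332). Both calls were also lost without wildtype replicate 1 (medians 0.426 and 0.219, adjusted p = 0.0925 and 0.0636) or 3 (medians 0.20 and 0.19, adjusted p = 0.266 and 0.236), and the neutrophil call without knockout replicate 3 (median 0.365, adjusted p = 0.0725). Other omissions raised the medians, to 0.86 and 0.39 without knockout replicate 1 (adjusted p = 1.43e-07 and 0.00146) and 0.76 and 0.36 without wildtype replicate 2 (adjusted p = 2.95e-05 and 0.000649). Without both wildtype replicates 1 and 2, which left 1 wildtype array, they were 0.82 and 0.36. Both calls were lost with array weights (medians 0.33 and 0.18, adjusted p = 0.136 and 0.208), with a stricter filter (medians 0.47 and 0.52, adjusted p = 0.0912 and 0.0725) and without wildtype replicate 1 and knockout replicate 4 together (medians 0.12 and 0.065, adjusted p = 0.778 and 0.376), and the monocyte call with camera on ranks (adjusted p = 0.147).

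Endothelial and mural cells lack CD45, which the sort required, and their markers were lower as a group, with a median of -0.36 and 18 of 19 tested genes below 0 (camera adjusted p = 1.05e-05, adjusted p = 0.684 with an estimated correlation). The efflux transporter Abcb1a differed by -0.85 (SE 0.22), VE-cadherin, Cdh5, by -0.72 (SE 0.21), Flt1 by -0.43 (SE 0.15) and Slco1a4 by -0.60 (SE 0.21). Array medians were 0.44 and 0.46 in wildtype replicates 1 and 2, -0.19 in wildtype replicate 3 and -0.19 to -0.05 in the knockout arrays. The median was -0.17 without wildtype replicate 2, -0.62 without wildtype replicate 3 and -0.24 without wildtype replicate 1 and knockout replicate 4 together (adjusted p = 0.0124). Without both wildtype replicates 1 and 2, picked as the highest in this list, 1 wildtype array was left and the median was -0.0019. At an unadjusted p under 0.05, limma counted 6 lower endothelial markers, 1 higher neutrophil marker and 5 higher monocyte markers, with 0 in the opposite direction in each list. Over all genes, and in the neutrophil and endothelial lists also when adjusted over the list alone, 0 passed.

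**Figure D3:**
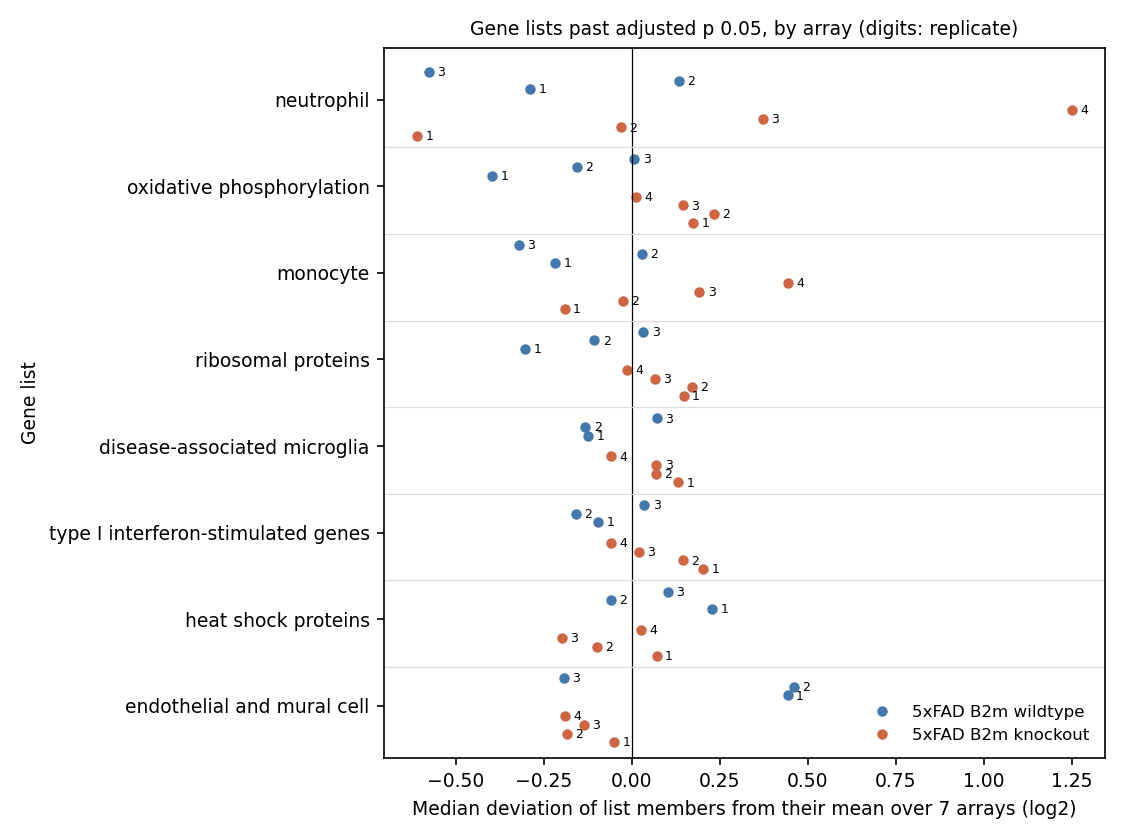
Median deviation (log2) of the members of each of the 8 lists past the threshold from their mean over the 7 arrays, with wildtype arrays in blue, knockout arrays in orange and the replicate number beside each point. Knockout replicate 4 reached 1.25 for neutrophil markers, and wildtype replicates 1 and 2 stood at 0.44 and 0.46 for endothelial markers.

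The remaining cell type lists did not pass in camera. Border-associated macrophage markers had a median of -0.12 over 15 genes (adjusted p = 0.217), with Siglec1 at -0.26 (SE 0.10). Dendritic cell markers had a median of 0.030 over 7 genes (adjusted p = 0.718), with Bst2 at 0.32 (SE 0.13). T cell markers had a median of -0.073 over 6 genes (adjusted p = 0.399), with Lef1 at -0.40 (SE 0.20). Oligodendrocyte markers had a median of -0.11 over 8 genes (adjusted p = 0.154), with the progenitor proteoglycan Cspg4 at -0.49 (SE 0.14), which passed in limma when adjusted over the list alone. Neuron markers had a median of -0.071 over 5 genes (adjusted p = 0.718), with Gad1 at -0.19 (SE 0.14). Astrocyte markers had a median of 0.14 and a mean of -0.013 over 5 genes (adjusted p = 0.993), with Clu at -0.35 (SE 0.17). Over the 45 distinct genes of these 6 lists, 0 passed in limma over all genes, and 1 was higher and 2 lower at an unadjusted p under 0.05. Apart from Cspg4, 0 passed when adjusted over the list alone.

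CD8 T cell, natural killer cell, B cell and erythroid markers left 2, 1, 4 and 2 tested genes and were not tested as lists. Their tested members had medians of 0.11, -0.15, -0.26 and -0.012, and Ebf1, a B lineage transcription factor, differed by -0.44 (SE 0.16). Most CD8 T cell markers were below the filter. In a limma fit without the filter, Cd8a was 7.39 ± 0.14 (SD, n = 3) in wildtype and 7.19 ± 0.032 (SD, n = 4) in knockout arrays (adjusted p = 0.577). Cxcr6, the chemokine receptor in the series title, was 6.59 ± 0.12 (SD, n = 3) and 6.50 ± 0.30 (SD, n = 4) (limma adjusted p = 0.907). The Cxcr6 values were near the median of the negative control rows, which lay between 6.15 and 6.35 in the 7 arrays, and the Cd8a means lay below their 75th percentile (7.5 to 7.7), so a difference in the few T cells such a gate can hold was not measurable here. Of the sex-linked genes, Eif2s3y, Kdm5d and Uty were measured, and their mean per array lay between 5.02 and 5.24 in all 7 arrays.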

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

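No tests in this part were chosen after the result was seen, but Tmem208 was among the genes picked for their small unadjusted limma p.

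In knockout replicate 1, Tmem208, a membrane protein of the endoplasmic reticulum, was 10.66 while the other 3 knockout arrays lay between 10.30 and 10.32. The gap to the nearest of them took 0.943 of the group's whole range, above the critical value of Dixon's test for 4 samples. It was the 1 result that stood out among 53 genes and list medians examined this way, where chance alone marks about 1 in 20. The 3 wildtype arrays were too few for this test. All 4 knockout values still exceeded the 3 wildtype values, and the difference of 0.72 did not pass correction (limma adjusted p = 0.265).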

How the results depend on the processing

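The tests that remove the gene span trend, leave out 2 arrays at a time, permute list medians, change the neighbourhood or leave the neighbours out of the fit were chosen after the results of the planned tests were seen. The alternative without wildtype replicates 1 and 2, counted among those below, left 1 wildtype array, so a call kept or lost in it decides nothing. B2m, Spint1, Gatm and Kcnip3 passed in each of 18 alternatives, and B2m differed by -3.06 to -2.92. The 2 genes higher became 1 (Gatm) with a stricter filter, which left Slamf7 untested, with centred arrays (Slamf7 adjusted p = 0.0504), without the gene span trend (0.0508), without the 2 arrays farthest out (0.0669) and with every row tested, and 0 with B2m and its 100 neighbours left out of the fit (0.158). The 3 genes lower, where B2m was in the fit, stayed 3 in those settings. Leaving out 1 array gave 1 to 7 genes higher and 3 to 19 lower, both highest without wildtype replicate 3. The 96 genes at an unadjusted p and 1.5-fold became 56 with a stricter filter and 58 (without wildtype replicate 1) to 249 (without wildtype replicate 3) without 1 array. At an unadjusted p alone, 70.3% of genes were higher, against 58.8% after repeated quantile normalization, 58.3% with centred arrays and 57.4% without the gene span trend. Of called genes 40% were higher, and 25% in the last 2 settings. The number of lists past the threshold, 8, became 5 with a stricter filter or array weights, 0 with an estimated correlation (smallest adjusted p 0.684), fry (0.452) or exact permutation of list medians (0.276), and 5 to 6 without 1 array, of which 4 to 6 were among the 8 (4 without wildtype replicate 1). Over 21 alternatives, the exact permutation left out, oxidative phosphorylation passed in 19, ribosomal proteins and endothelial markers in 18, the disease-associated list in 16, the interferon list in 13, neutrophil and monocyte markers in 12 and heat shock proteins in 11. The share of called genes near B2m stayed past the threshold in its alternatives, with Fisher's exact p of at most 0.0198 for 25 neighbours on each side, where Gatm was the 1 called neighbour left. At an unadjusted p the Fisher's exact p was at most 0.0352, for 100 on each side. Signs turned for genes that passed in no setting. Without wildtype replicates 1 and 2, H2-T22 was -0.058, Ndrg1 0.12, Lef1 0.14, Cd5 -0.053, Batf3 -0.12, Cd209a -0.21, Mal 0.27 and Nrgn 0.060. Without the 2 arrays farthest out, Cd209a was -0.072, Slc4a4 -0.056 and Alas2 -0.11, and with array weights Cd4 was 0.010 and Alas2 -0.083. Leaving out 1 array gave -0.025 to 0.17 for Cd5, -0.18 to 0.026 for Cd4 and -0.040 to 0.26 for Cd209a. The cause of these changes was not tested. The windows in megabases around B2m were not run, since no build was named for the array, nor the sex covariate, since Y-linked genes varied by 0.219. No paired analysis was possible because replicate numbers follow deposit order only. Levels near the negative control rows, such as Spint1 and Kcnip3 in knockout arrays and Slamf7 in both genotypes, give differences that can understate the change.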

Other observations

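All tests in this part were chosen after the results they bear on were seen, except that the splits of the arrays for the 5 called genes, the 96 genes and the 8 lists were set beforehand, and the gene span test of the oxidative phosphorylation list, though chosen after the list's difference was seen, was set before its own result was.

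Slamf7 was the called gene that lay away from B2m, within a cluster of related receptor genes on chromosome 1. Its relatives there, Ly9, Cd48, Slamf1, Cd84, Slamf6 and Cd244a, named after their values were seen, differed by -0.075 to 0.19, with a lowest unadjusted limma p of 0.268. Of the 20 tested genes nearest to Slamf7, 0 reached an unadjusted p under 0.05 in limma. Among the 9274 rows with no listed gene, 0 passed in a limma fit of their own and 556 reached an unadjusted p under 0.05. How many of them are among the 5222 negative and 1324 positive control rows was not counted, so they cannot be read as unannotated transcripts alone.

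Gatm, Spint1 and Kcnip3, 3 of the 4 called genes other than B2m, lay among the 100 tested neighbours of B2m. Placement without regard to B2m is argued against by Fisher's exact test (p = 3.85e-06). A candidate explanation is donor-strain DNA that stays linked to a targeted allele, and the share at an unadjusted p under 0.05 was also raised among the 50 nearest neighbours (28.0% against 11.8%, Fisher's exact test, p = 0.0016). Probe mismatches to donor-strain sequence weaken hybridization and so are argued against for Gatm, which rose by 1.95, but for Spint1 (-4.75) and Kcnip3 they cannot be told apart from lower transcript levels, because values per probe were not used here. An effect of B2m loss itself on these genes, or of the altered allele on nearby genes, stays open as untested.

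The oxidative phosphorylation list was higher in knockout samples and the ribosomal protein list moved with it. Without wildtype replicate 1 the medians were 0.221 and 0.127, against 0.329 and 0.214 with it, so that array did not carry the whole difference. Both lists still passed in camera with the preset correlation of 0.01. The correlations estimated for the lists were 0.573 and 0.636, so those calls cannot tell genotype from swings of single arrays. Without wildtype replicates 1 and 2 together, which left 1 wildtype array, the ribosomal median was 0.052. With the gene span trend removed the medians were 0.273 and 0.139, so that trend, as removed here, did not carry the whole difference either. An effect of genotype may account for the first list, whose array medians separated the genotypes (exact permutation p = 0.0286, adjusted p = 0.276). That separation was narrow, with 0.007 in wildtype replicate 3 and 0.013 in knockout replicate 4. The array medians of cholesterol synthesis and cell cycle, which camera did not call, also separated the genotypes. For ribosomal proteins the exact permutation p of 0.0857 cannot tell genotype from differences between single arrays. Neither call held in camera with an estimated correlation (adjusted p = 0.684), so a shared swing of each list between arrays stays open, as does the RNA quality of single samples, which was not tested.

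The medians of neutrophil and monocyte markers were higher and that of endothelial markers lower in knockout samples. Of 12 monocyte markers, 5 lay below 0. Another list held 0 of 17 neutrophil, 3 of 12 monocyte and 1 of 19 endothelial markers. A lower share of microglia in the knockout sorts cannot be judged from these lists. More neutrophils alone would lower that share without raising endothelial markers. The medians of the neutrophil and endothelial lists went opposite ways and differed by 0.833. Their interquartile ranges over genes, each divided by 2, add up to 0.389. The directions were known when this comparison was made, and genes are not independent replicates. By array medians, the exact permutation p was 0.429 for neutrophil and 0.143 for endothelial markers. The opposite moves therefore describe these arrays and argue against no cause. Neutrophil RNA in knockout replicate 4, from cells the CD45 and CD11b gate does not exclude, is a candidate for the first part. The neutrophil median was 0.0937 without that array. It was picked for its high neutrophil markers, so that fall restates the observation and does not test the cause. S100a8, itself such a marker, was 12.44 in it against 10.56 to 11.87 in the other knockout arrays. Endothelial RNA in wildtype replicates 1 and 2, which a CD45 sort should remove, is a candidate for the second part. The median was -0.00192 without both, which left 1 wildtype array. These arrays were picked for their high endothelial markers, so that fall restates the observation and does not test the cause. Flt1, itself such a marker, was 11.29 and 11.19 in them against 10.63 in wildtype replicate 3. The neutrophil median was 0.474 with all arrays and 0.20 without wildtype replicate 3, where the call was lost (adjusted p = 0.266). The call was also lost without wildtype replicate 1 (median 0.426, 0.0925) or knockout replicate 3 (median 0.365, 0.0725), with smaller moves of the median. The median was 0.86 without knockout replicate 1 and 0.76 without wildtype replicate 2, so single arrays other than knockout replicate 4 also moved it. A genotype effect on these cells stays open as untested.

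The number of calls was examined over all 35 splits into 3 and 4, where the smallest possible share is 0.0286. The deletion fixed the call of B2m in the real split, so the count was also made with B2m left out of the fit. For the 5 called genes with B2m and the 4 without it, 1 split, the real one, gave as many, and the highest other count was 2. That is a share of 0.0286, the smallest possible, which argues against chance for these counts without excluding it. Of the 4, 3 are neighbours of B2m that may follow its allele, so this bears on no wider effect of genotype and does not exclude chance for Slamf7. With B2m and its 100 tested neighbours left out, the real split called 0 genes in limma with 1171 at an unadjusted p under 0.05 (highest other count 2), a count that all 35 splits reach and that therefore decides nothing. Chance cannot be excluded for the 1193 genes at an unadjusted p, since 3 splits gave as many and the highest other count was 1679, nor for the 96 genes that were also at least 1.5-fold, since 3 splits gave as many, up to 140. Both highest counts came when wildtype replicates 1 and 2 and knockout replicate 4, the arrays whose deviations correlated positively with gene span, were set against the rest. For the 8 lists chance cannot be excluded either, since 11 splits gave as many and the highest other count was 12.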
